A study of Homo sapiens with 18 samples.

How the data were processed

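The deposited files hold raw counts per gene. For the knockdown experiment these counts were made with featureCounts 2.0.1 on paired reads, reverse-stranded, with exons summed by gene, per the file headers. Reads had been trimmed with Trimmomatic and GRCh38 was the genome, per the submitters' processing notes, and the aligner is not given in the sources used here. The authors deposited the counts of the other 2 experiments as tables without a record of how they were counted, so their strand setting is unknown and genes that overlap on opposite strands are uncertain there. RNA came from TRIzol extraction of total RNA. The tables held 60623 gene identifiers for the knockdown experiment and 58884 for the other 2, of which 60592 and 58861 had a symbol, 297 and 389 of them named from GENCODE 29. All 18 libraries were used in 9 groups of 2, with 0 columns unused.

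The comparisons, the gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, except where stated otherwise. Each experiment was fitted on its own with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with TMM factors, filterByExpr by group and a quasi-likelihood F-test with 1 coefficient per group and no replicate block, so that all groups of an experiment shared the spread. Residual degrees of freedom were 2, 4 and 3 for the knockdown, CDK6 and inhibitor experiments, and the common biological coefficients of variation were 0.320, 0.144 and 0.129. In all, 7 comparisons were tested, and p-values were adjusted by the method of Benjamini and Hochberg within each, with calls at an adjusted p below 0.05. The difference between the lines was tested as an interaction. Log2 fold changes are given with standard errors, worked back from the test as the absolute log2 fold change over the square root of F. CPM in the 7 comparisons are scaled by TMM with SD over n = 2, and CPM named as of the library total are not. DESeq2 1.42.0 served as an alternative.

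The 29 gene lists held 801 symbols, and a list needed 5 tested members for a set test. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation camera takes its p-value from the residual degrees of freedom (2, 4 and 3 for the knockdown, CDK6 and inhibitor experiments). So few leave it little power after adjustment over the lists. A list that did not pass there is therefore not shown to be unchanged. Members were counted as up or down by the gene test, adjusted over all genes and adjusted over the list alone. Only members that passed the filter were counted. A member near 0 counts in the controls could pass it only through a group where it was higher, so shares of such markers do not test their list. The named genes were 16 genes given in every comparison, the 8 largest rises and 8 largest falls among called genes with at least 10 CPM in the higher group and no overlap between groups (6 each for the interaction), and up to 4 members of each described list. Where a group had 0 counts, the fold is given as at least the value with 3 counts over that group (0.0493 to 0.168 CPM per library for 3 counts), and with 1 to 3 counts as a ratio with its 95% counting interval. Such floors and intervals cover counting error only.

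Since no gene was called for the knockdown, the planned sets of knockdown calls were empty and the planned sets of the 200 genes with the lowest p in each direction were used. The alternatives were DESeq2 size factors, library totals alone and upper-quartile factors in edgeR, no filter, at least 1 CPM or 10 CPM in 2 libraries, a fit without each library, a replicate block, only the groups compared, and the DESeq2 Wald test. Chosen after the data were seen were a fit without mitochondrial genes, knockdown sets from the fit without vector replicate 2, and list member counts in each fit without a library. With 2 libraries per group no test of single libraries within a group was possible.

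In a self-test, 100 genes were given a 1.5-fold and 100 a 3-fold change in simulated counts with the spread of each experiment. The share recovered at 1.5-fold and 3-fold was 0 and 33% for the knockdown, 25 and 89% for PIK75 in MCF-7 with CDK6, 22 and 94% in T-47D with CDK6, 4 and 79% for the interaction, 15 and 99% for PIK75 in T-47D, 29 and 99% for THZ1, and 21 and 100% for PIK75 against THZ1. Between 3 and 13 unchanged genes were called in these runs. The changed genes were well counted and all others were left unchanged, so the adjusted threshold was stricter here than where most genes are called. The shares therefore do not give the power of the inhibitor comparisons on the real data.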

Results

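Count tables of 18 libraries from the hormone receptor-positive breast cancer lines MCF-7 and T-47D were analysed as 3 separate experiments with 9 groups of n = 2. The knockdown experiment held T-47D cells with an empty vector or an shRNA against CDK7, at 42650397 to 60840057 counts per library. The second experiment held MCF-7 and T-47D cells overexpressing CDK6, under DMSO or PIK75, at 20227912 to 34421641 counts. The third held T-47D cells under DMSO, PIK75 or THZ1, at 17878757 to 25679360 counts. As background, PIK75 was made as an inhibitor of the PI3-kinase p110α and has also been reported to act on CDK7 and CDK9, whereas THZ1 is a covalent inhibitor of CDK7 that also binds CDK12 and CDK13. The compounds are therefore different chemotypes and not analogs, and their doses and times are not in the labels. The design text names a pair of hairpins, so the 2 knockdown libraries may carry different ones. Nothing in the labels says that replicates were separate cultures, so each p-value measures only the spread between these samples. Genes were tested in 7 comparisons, and 29 gene lists were tested within each, with adjustment by the method of Benjamini and Hochberg at 0.05.

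The lines kept the marks known for them. MTAP, deleted in MCF-7, lay at no more than 0.732 counts per 1e6 (CPM) in the MCF-7 libraries and reached 55.6 CPM in T-47D, and CDKN2A, deleted with it, lay at 1.24 to 1.78 and at 11.4 to 33.1 CPM. CDK6 (ENSG00000105810, chromosome 7 at 92604921–92836594, minus strand, GRCh38) reached 382 and 296 CPM in T-47D cells overexpressing it under DMSO, against 6.69 and 6.96 CPM in plain T-47D cells under DMSO. In the MCF-7 overexpression libraries it reached 68.7 and 58.8 CPM under DMSO, and no MCF-7 library without overexpression was there to size the step.

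CDK7 (ENSG00000134058, chromosome 5 at 69234795–69277430, plus strand) was measured in every library before the knockdown was used. It lay at 28.6 and 38.8 CPM of the library total with the vector and at 9.90 and 11.5 CPM with the hairpins. PIK75 went with lower CDK7 in each setting, at 16.9 and 12.4 CPM against 31.9 and 34.1 in MCF-7 with CDK6, and at 8.04 and 10.2 against 40.9 and 44.7 in T-47D with CDK6. In plain T-47D cells CDK7 lay at 38.2 and 39.5 CPM under DMSO, 7.55 and 9.16 under PIK75 and 14.2 and 9.35 under THZ1. CDK7 mRNA itself was thus lower under both compounds.

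**Figure D1:**
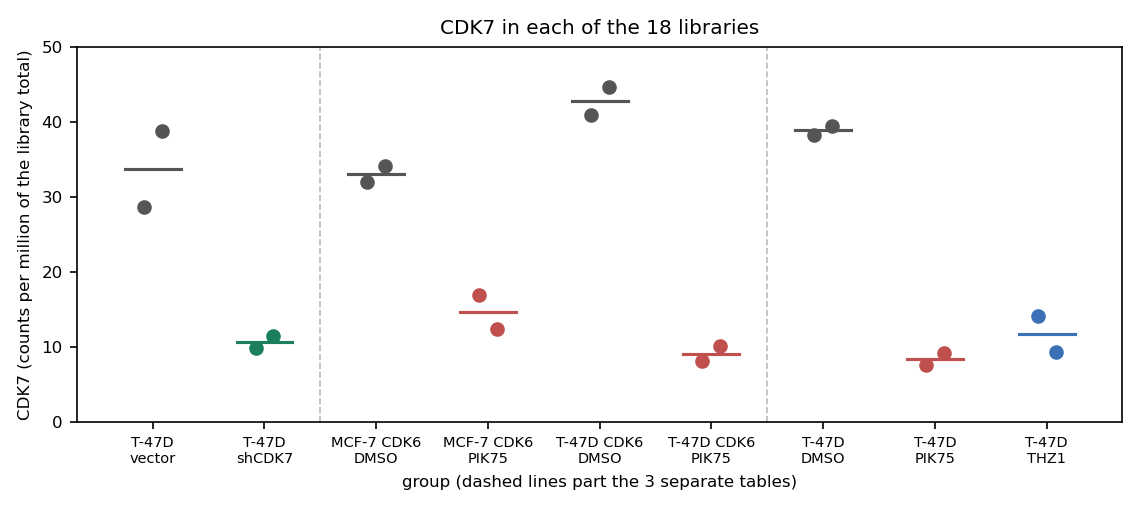
CDK7 in each of the 18 libraries, in untransformed CPM of the library total; points are libraries, short lines are group means and dashed lines part the 3 experiments. CDK7 lay at 9.90 and 11.5 CPM after knockdown against 28.6 and 38.8 with the vector. It was lower than under DMSO with PIK75 in every setting, and with THZ1 in plain T-47D cells, where alone THZ1 was used.

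The first comparison asked what loss of CDK7 changed in T-47D cells. No gene passed the adjusted threshold in edgeR among 17840 tested, while 564 had an unadjusted p below 0.05 and DESeq2 called 43. Without a filter on low counts edgeR called 499 (63 up, 436 down). The count depended on vector replicate 2, which stood apart from the other 3 libraries. Without it 82 genes were called (33 up, 49 down), without vector replicate 1 the call count was 4257 (2192 up, 2065 down), and without either knockdown library it was 0. The control group thus set how many genes could be called, and fold changes are given here as values.

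CDK7 had a log2 fold change of -1.65 ± 0.23 (standard error) with adjusted p = 0.985 and an unadjusted p of 9.3e-04 by the quasi-likelihood test, and it was called without vector replicate 1 (-1.81, adjusted p = 1.6e-04) and without vector replicate 2 (-1.45, adjusted p = 0.0098). No Hippo effector was called, with YAP1 at -0.08 ± 0.22, WWTR1 at 0.47 ± 0.19 and TEAD4 at 0.34. The YAP target genes CCN1 and CCN2, which encode matricellular proteins, had values of 0.26 and 0.29 ± 1.03, and ANKRD1 had -0.36. CCN2 was called only without vector replicate 1 (2.58). Of receptor and cell-cycle genes, ESR1 had 0.33 ± 0.19, PGR 0.46 ± 0.21, CCND1 0.19, E2F1 0.64 ± 0.98, CCNE1 0.68, RB1 0.12, CDK6 0.00, MYC 0.02 and MCL1 0.38. E2F1 and CCNE1 were called only without vector replicate 1, at 3.11 and 2.48.

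A few genes kept their direction and were called once vector replicate 2 was left out. BCL2, an anti-apoptotic oestrogen receptor target, had -1.50 ± 0.32 (-1.74, adjusted p = 0.012 without that library), and the fatty acid elongase ELOVL2 had -2.64 ± 0.29 (-2.86, adjusted p = 7.0e-04). The potassium channel KCNK5 had 1.43 ± 0.30 (1.58, adjusted p = 0.036). PTPRC, a leukocyte marker, was at least 82.0-fold lower with the hairpins, but it fell below the filter without vector replicate 1 and so rests on that library. Adjusted over the list alone, CDK7 and ELOVL2 fell and MT-ND6 rose (1.17 ± 0.22).

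Lists of the knockdown comparison leaned with vector replicate 2. The unfolded protein and integrated stress response list had a median of -1.23 and 0 of its members called (camera adjusted p = 9.8e-17, but adjusted p = 0.70 with an estimated correlation). Its median was -0.20 without vector replicate 2 and -1.74, with 29 members down, without vector replicate 1. Interferon-stimulated genes such as HERC5 (-2.65 ± 0.60) and HERC6 (-2.23 ± 0.58) had a median of -0.79 (4.1e-10 by camera, adjusted p = 0.70 with an estimated correlation), which was -0.27 without vector replicate 2. Proliferation lists went the other way. G1/S genes had a median of 0.47 and G2/M genes 0.41, with camera adjusted p of 1.2e-06 and 1.0e-07 that both became adjusted p = 0.75 with an estimated correlation. Without vector replicate 2 these medians changed sign, to -0.26 and -0.21, and without vector replicate 1 they were 2.26 and 1.57 with 32 and 34 members up. YAP/TAZ target genes had a median of 0.09 with 0 of 18 called (camera adjusted p = 0.19), and 7 up and 3 down without vector replicate 1. The self-test recovered 33% of added 3-fold changes here and 0% of 1.5-fold changes, so an absent call says little about changes of those sizes.

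**Figure D2:**
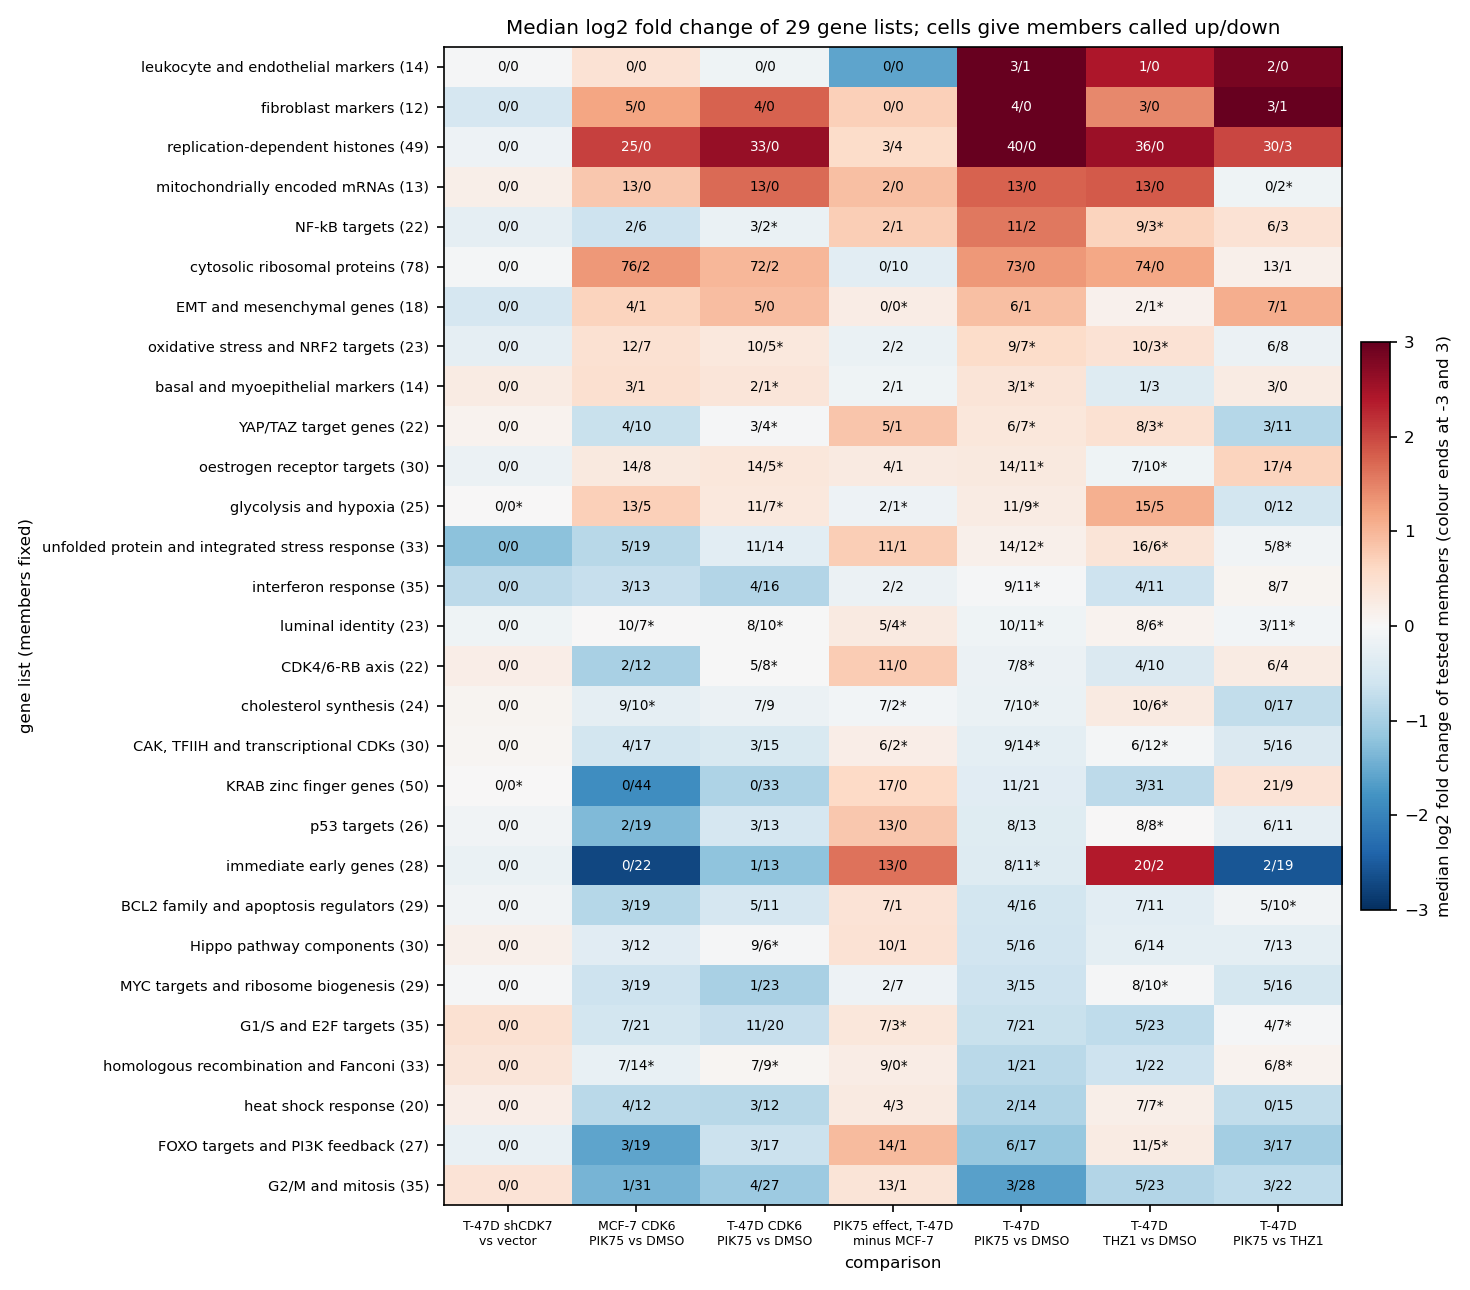
Median log2 fold change of 29 gene lists in 7 comparisons, coloured from -3 to 3, with the number of members called up and down in each cell; an asterisk marks a list whose median or majority of calls changed direction under another scaling. Relative to the other genes, histone, ribosomal protein and mitochondrial genes rose under both compounds. Immediate-early genes fell under PIK75 in MCF-7 (0 up, 22 down) and rose under THZ1 (20 up, 2 down). The colours of fibroblast and leukocyte markers rest on genes near 0 counts.

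The second comparison asked how PIK75 changed MCF-7 cells overexpressing CDK6. Of 18767 genes tested, 10229 changed (4735 up, 5494 down), and 2325 rose and 3639 fell at least 2-fold. The share of calls that were up moved with scaling, from 46.3% with TMM to 32.5% with library totals alone (3224 up, 6689 down) and to 62.2% with upper-quartile factors (6803 up, 4126 down), so directions are relative to the bulk of the genes. The median over all genes was 0.00 with TMM and -0.21 with totals alone. No spike-in was available, so a general loss of mRNA under the compounds cannot be measured. In every inhibitor comparison a rise may thus be a smaller loss than that of the other genes. Among genes with at least 10 CPM in the higher group and no overlap between groups, the sharpest losses were in BAMBI (-6.98 ± 0.35), FLRT3 (-6.27), FADD (-6.09), HPS6 (-6.05), ZFP36L2 (-5.97), DKK1 (-5.80 ± 0.16), B3GNT2 (-5.74) and ZBTB6 (-5.65). FADD had 6 counts under PIK75 against 543, and its -11.25 without PIK75 replicate 1 is a fitted value at or near 0 counts and no fold. BAMBI and DKK1 regulate TGF-β and Wnt signalling. The largest rises of such genes were in 5.8S ribosomal RNA and the microRNA gene MIR3648-1 (8.57 for RNA5-8SN3, 8.24 for RNA5-8SN1 and 7.83), which have near-identical copies and so uncertain read placement, and in RASL11A (4.74 ± 0.43), H2AC8 (5.15 ± 0.39), TBX4 (3.81), H3C10 (3.14) and H2BC8.

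YAP targets CCN1 (ENSG00000142871, chromosome 1 at 85580761–85583950, plus strand) and CCN2 (ENSG00000118523, chromosome 6 at 131948176–131951372, minus strand) fell in MCF-7 (-2.91 ± 0.85, adjusted p = 0.014, and -3.89 ± 0.88, adjusted p = 0.0033). The call of CCN1 was lost without PIK75 replicate 1 (-2.30, adjusted p = 0.12). MCL1 (ENSG00000143384, chromosome 1 at 150574551–150579738, minus strand) fell from 545 to 73.5 CPM (-2.89 ± 0.14, adjusted p = 8.7e-08), and MYC (ENSG00000136997, chromosome 8 at 127735434–127742951, plus strand) from 90.1 to 11.3 CPM (adjusted p = 2.0e-04). CCNE1 (-3.23 ± 0.24), CCND1 (-0.91 ± 0.15, or -0.56 without DMSO replicate 1) and CDK7 (-0.91 ± 0.18) fell and ESR1 rose (0.60 ± 0.10). The Hippo effectors themselves had small values that did not pass, at -0.13 for YAP1, -0.23 for WWTR1 and -0.25 for TEAD4, as had CDK6 (0.01), RB1 (0.05), E2F1 (-0.24) and PGR (0.03, but 0.51 and called without DMSO replicate 1, adjusted p = 0.024). ANKRD1 had 0 counts against 4.

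Immediate-early genes, the quickest responders to growth signals, fell with 22 of 28 down and 0 up (median -2.72, camera adjusted p = 6.3e-07, but adjusted p = 0.33 with an estimated correlation), including DUSP5 (-5.54), DUSP1 (-4.82) and DUSP6 (-4.43). KRAB zinc-finger genes fell with 44 of 50 down (median -1.86, or -1.77 with genes at 0 set to their bound, camera adjusted p = 3.9e-10, adjusted p = 0.21 with an estimated correlation). G2/M genes fell with 31 of 35 down (median -1.40, 4.0e-16 and 0.33), led by AURKA (-4.57), TTK (-3.22) and PLK1 (-2.88), and 21 of 35 G1/S genes fell and 7 rose (CDC25A -3.55, FEN1 -2.80; 0.029 and 0.65). FOXO targets (19 down, 3 up of 27; 5.0e-06 and 0.33) and heat-shock genes (12 down, 4 up of 20; 3.0e-04 and 0.43) had more falls than rises, with CITED2 at -5.25 and DNAJB1 at -5.04. Genes of the CDK-activating kinase, TFIIH and transcriptional CDKs fell in 17 of 30 cases and rose in 4, among them CCNT1 (-4.10), HEXIM1 (-2.68) and CDK9 (-2.13), with camera adjusted p = 0.0071 and adjusted p = 0.33 with an estimated correlation. Apoptosis regulators of the BCL2 family fell in 19 of 29 cases and rose in 3 (BMF -3.07, PMAIP1 -2.79), or 20 and 3 adjusted over the list alone.

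Ribosomal protein genes rose in 76 of 78 cases (median 1.31, camera adjusted p = 8.1e-42, adjusted p = 0.33 with an estimated correlation), as RPL18A (1.61) and RPS19 (1.58) did. Replication-dependent histone genes rose in 25 of 41 cases (median 2.06, or 2.00 with genes at 0 set to their bound; 14 without PIK75 replicate 1), H2BC14 by 5.36. All 13 mitochondrially encoded protein genes rose (median 0.82, MT-CO3 1.11), but only 4 were called without DMSO replicate 1 and 2 without PIK75 replicate 2. YAP/TAZ target genes gave 4 up and 10 down of 20, with 5 down without PIK75 replicate 1, a median of -0.66 that shrank to -0.18 with genes at 0 set to their bound (-0.50 to -0.25 in the fits without 1 library, the smallest without PIK75 replicate 1), camera adjusted p = 0.56 and fry adjusted p = 0.033. FJX1 (-4.73) and GADD45A (-3.42) fell in that list, while AMOTL2 (-2.73) and LATS1 (-1.98) fell among the Hippo components (3 up, 12 down of 29). Oestrogen receptor targets had 14 up and 8 down with a median of 0.30 and a mean of -0.15, and 8 up without PIK75 replicate 1. All 5 tested fibroblast markers rose from near 0 counts, 3 of them without PIK75 replicate 2, with COL1A2 at a ratio of 24.5 (95% counting interval 3.9 to 1019) and COL3A1 at 1.55 log2 units. COL1A2 had 6.86 log2 units without DMSO replicate 1, a fitted value near 0 counts and no fold. Its call was lost without DMSO replicate 2 or without PIK75 replicate 2, and no leukocyte or endothelial marker was called. The self-test recovered 25% of 1.5-fold and 89% of 3-fold changes.

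The third comparison asked the same of T-47D cells overexpressing CDK6. PIK75 changed 9524 of 18767 genes (4860 up, 4664 down), and 2133 rose and 2670 fell at least 2-fold. Up calls made up 51.0% with TMM and 21.1% with totals alone (2038 up, 7613 down), where the median over all genes was -0.41 against 0.06. CDK7 fell (-1.73 ± 0.18, adjusted p = 2.7e-05) and so did MCL1 (-1.08 ± 0.13), CCNE1 (-1.59 ± 0.23) and TEAD4 (-0.86 ± 0.14). ESR1 (ENSG00000091831, chromosome 6 at 151656691–152129619, plus strand) rose by 1.22 ± 0.10. RB1 rose by 0.54 ± 0.09, although it had 0.04 with totals alone (adjusted p = 0.77). Small rises were seen for WWTR1 (0.49 ± 0.10, adjusted p = 0.0021, lost without DMSO replicate 1 at 0.063, and turning to -0.01 with totals alone) and for YAP1 (0.28 ± 0.11, adjusted p = 0.047, lost at 0.18, 0.36 and 0.26 without DMSO replicate 1, DMSO replicate 2 or PIK75 replicate 1, and turning to -0.21 with totals alone). PGR (0.58 ± 0.19, adjusted p = 0.023) lost its call without DMSO replicate 1 (0.082), DMSO replicate 2 (0.15) or PIK75 replicate 1 (0.085) and with totals alone (0.74). CDK6 fell by 0.45 ± 0.15 (adjusted p = 0.027), with the call lost without DMSO replicate 1 (0.17) or PIK75 replicate 2 (0.097) and with upper-quartile factors (0.13).

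CCN1 was not called in this group because its PIK75 replicates stood at 100.3 and 11.9 CPM of the library total. Its value of 1.18 ± 0.66 became 1.99 (adjusted p = 2.4e-04) without PIK75 replicate 2 and -1.01 (adjusted p = 0.038) without PIK75 replicate 1. CCN2 (0.75) also changed sign between these fits. Among the fits without 1 library, MYC (-0.79) was called only without PIK75 replicate 1 (-2.03). CCND1 (-0.09), E2F1 (0.07) and ANKRD1 (-0.45) were not called. With totals alone E2F1 was called as a fall by the quasi-likelihood test (-0.43, adjusted p = 0.012). YAP/TAZ targets as a list had 3 up and 4 down of 20 (median -0.03, camera adjusted p = 0.86), or 3 and 3 adjusted over the list alone. Their balance turned with scaling (5 up, 3 down with DESeq2 size factors; 6 and 3 with upper-quartile factors) and was 5 up and 3 down without PIK75 replicate 2, with 6 down without PIK75 replicate 1. FJX1 (-2.70) and GADD45A (-2.43) fell and MYOF (0.80) rose in it.

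The haematopoietic actin regulator NCKAP1L rose at least 480-fold from 0 counts, to 18.3 ± 19.5 CPM (SD, n = 2). RNA5-8SN3 (8.48), RNA5-8SN1 (8.04), RASL11A (6.95 ± 0.45), NRP2 (6.48), TP53AIP1 (6.26), DIO2 (6.21) and H4C5 (4.41, or 2.78 without PIK75 replicate 1) also rose. With at least 10 CPM and no overlap between groups, the sharpest falls were in MAP1S (-4.81), HPS6 (-4.50, or -7.34 without PIK75 replicate 1), IRF2BP1 (-4.26), RHOV (-3.96), RPUSD2 (-3.75), CLDN4 (-3.73), ADPRS (-3.62) and FZD2 (-3.51). G2/M genes fell in 27 of 35 cases and rose in 4 (median -1.09, camera adjusted p = 6.0e-13, adjusted p = 0.43 with an estimated correlation), led by PLK1 (-2.71) and CCNB1 (-2.48). MYC targets and ribosome biogenesis genes fell in 23 of 29 cases (median -0.97, 3.0e-10 and 0.42), with NOP16 at -3.47. KRAB zinc-finger genes fell in 33 of 50 cases, or 35 adjusted over the list alone, and immediate-early genes in 13 of 28 with 1 up (median -1.20, or -0.91 with genes at 0 set to their bound), fewer than in MCF-7. Heat-shock genes fell in 12 of 20 cases, HSPA8 by 2.77 log2 units, and interferon-stimulated genes in 16 of 35. The CDK4/6-RB list had 5 up and 8 down, which turned to 7 up and 3 down with upper-quartile factors, with 2 up and 5 down without DMSO replicate 1, 5 down without DMSO replicate 2 and 4 down without PIK75 replicate 2.

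Histone genes rose in 33 of 41 cases (median 2.62, camera adjusted p = 1.3e-05, adjusted p = 0.62 with an estimated correlation; 18 without PIK75 replicate 1), with H1-1 at least 151-fold up (not called by DESeq2, 0.078) and H2BC14 at a ratio of 192 (95% counting interval 52.5 to 1594). Ribosomal protein genes rose in 72 of 78 cases (median 0.99, 1.0e-28 and 0.43), RPS28 by 1.36 and RPLP1 by 1.34, and all 13 mitochondrially encoded protein genes rose (median 1.70, MT-ND4 2.01, MT-CO2 1.92). Hippo components had 9 up and 6 down, turning to 0 up and 13 down with totals alone and to 4 up and 4 down without DMSO replicate 1 and 4 up and 5 down without DMSO replicate 2. Of the 5 fibroblast markers that passed the filter 4 rose, COL1A2 at a ratio of 82.6 (27.8 to 405) and COL3A1 by 2.80. The self-test recovered 22% of 1.5-fold and 94% of 3-fold changes.

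The fourth comparison tested the difference between the lines itself. The effect of PIK75 differed between T-47D and MCF-7 cells for 3107 genes (2353 with the higher log2 fold change in T-47D, 754 with the lower), 1318 and 298 of them at least 2-fold. The balance depended on scaling, with 75.7% higher in T-47D with TMM, 63.8% with DESeq2 size factors (1970 and 1118), 52.9% with upper-quartile factors (1681 and 1497), 45.8% with totals alone (1520 and 1796) and 49.2% after all mitochondrial genes were left out (1618 and 1674). The count ranged from 1480 without T-47D DMSO replicate 2 and 1565 without T-47D DMSO replicate 1 to 2023 and 2099 without MCF-7 DMSO replicate 1 or DMSO replicate 2, and 3492 without T-47D PIK75 replicate 2. Of these genes, 266 were called in both lines in opposite directions, 196 up in T-47D and down in MCF-7 and 70 the reverse, and 1345 were called in both in one direction.

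MCL1 fell in both lines but less in T-47D (difference 1.81 ± 0.18, adjusted p = 1.6e-04), and this kept its call in every alternative. CCN1 (4.10 ± 1.08, adjusted p = 0.026), CCN2 (4.64 ± 1.24, 0.027) and MYC (2.20 ± 0.59, 0.027) had higher values in T-47D, and each lost its call in most fits without 1 library, for example CCN1 at 0.13 and MYC at 0.10 without MCF-7 PIK75 replicate 1 and CCN2 at 0.38 without T-47D PIK75 replicate 1. MYC also lost it with DESeq2 (0.074). Without T-47D PIK75 replicate 1 the differences were 1.91 for CCN1, 2.47 for CCN2 and 0.98 for MYC. Under DMSO CCN2 lay at 1.14 and 0.494 CPM of the library total in T-47D and at 5.14 and 17.2 in MCF-7. It thus had less room to fall in T-47D. WWTR1 (0.72, lost at 0.13 without MCF-7 DMSO replicate 1), ESR1 (0.62, lost at 0.12 without it), CCND1 (0.82, lost at 0.21 without it and at 0.089 with totals alone), RB1 (0.48, lost at 0.25 without it and at 0.26 with totals alone) and CCNE1 (1.64, lost at 0.066 without MCF-7 DMSO replicate 2) were higher in T-47D, and CDK7 was lower (-0.82 ± 0.25, adjusted p = 0.049, lost at 0.18 without MCF-7 PIK75 replicate 1). YAP1 (0.41), TEAD4 (-0.61), CDK6 (-0.46), PGR (0.55) and E2F1 (0.32) did not pass. ANKRD1 did not pass either, and no difference is given since it had 0 counts in MCF-7 under PIK75.

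Immediate-early genes again marked the difference, with 13 of 28 higher in T-47D and 0 lower, or 15 and 0 adjusted over the list alone (camera adjusted p = 5.0e-05, at least 0.56 for every list with an estimated correlation). EGR1 differed by 4.86 and DUSP5 by 3.00. Of the members, FOS lay at 38.2 and 51.9 CPM of the library total under DMSO in MCF-7 and at 0.916 and 2.21 in T-47D. MYC lay at 94.6 and 105 against 66.4 and 73.3. A gene near 0 in T-47D had less room to fall, and how far this shaped the list was not tested. Only 5 members were called without T-47D DMSO replicate 1, and 7, 7, 8 and 7 without MCF-7 DMSO replicate 2, MCF-7 PIK75 replicate 1, MCF-7 PIK75 replicate 2 or T-47D DMSO replicate 2. FOXO targets had 14 higher and 1 lower of 27 (CITED2 3.66), with 8 higher without T-47D DMSO replicate 2. The CDK4/6-RB list had 11 higher and 0 lower of 20, led by CDKN1B (4.20), with 3 without T-47D DMSO replicate 1 or DMSO replicate 2, 4 and 5 without MCF-7 DMSO replicate 1 or DMSO replicate 2, and 7 without MCF-7 PIK75 replicate 2. Among genes near 0 in one line, TSPYL5, SDR42E1, SOX21 and CGAS had only 4 to 28 counts in T-47D and no fold is given. SOX21 and TSPYL5 lost their calls without T-47D PIK75 replicate 2 (0.17 and 1.0), and SOX21 was at 0.050 without T-47D DMSO replicate 2. DIO2 (7.50) and SOX2 (7.38) were higher in T-47D, and LPAR1 (-3.56), GNAI1 (-3.20), ABCC6 (-3.19), H2BC8 (-3.08) and SMO (-6.26, lost at 0.082 without MCF-7 PIK75 replicate 2) lower. GJC1 (-4.78) had its sign turned to 1.66 without MCF-7 PIK75 replicate 2. YAP/TAZ targets had 5 higher and 1 lower of 20 (median 0.84, or 0.28 to 0.83 in the fits without 1 library, camera adjusted p = 0.50), and 0 higher without T-47D DMSO replicate 1 or DMSO replicate 2, 2 higher without either MCF-7 DMSO library or MCF-7 PIK75 replicate 2, and 3 without MCF-7 PIK75 replicate 1. The self-test recovered 4% of 1.5-fold and 79% of 3-fold differences, so equal effects cannot be claimed where no difference was called.

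The fifth comparison asked how PIK75 changed T-47D cells without CDK6 overexpression. It changed 12892 of 18239 genes (6955 up, 5937 down), and 5240 rose and 4073 fell at least 2-fold. Of the calls 53.9% were up with TMM and 33.6% with totals alone (4393 up, 8696 down), where the median over all genes was -0.54 against 0.12. With at least 10 CPM and no overlap between groups, the largest rises came from genes silent in DMSO, namely NCKAP1L (at least 2300-fold, to 129 ± 18.4 CPM, SD, n = 2), H1-1 (at least 476-fold), SAMSN1 (435), CAMK2A (396), LGR5 (393), MGAM2 (392), GUCA1A (324) and CRHR2 (288). NCKAP1L and SAMSN1 are blood-cell genes, CAMK2A is neuronal and GUCA1A belongs to photoreceptors. NCKAP1L, H1-1, CAMK2A and GUCA1A lay within 200 kb downstream of an expressed gene on their strand. SAMSN1, MGAM2, LGR5 and CRHR2 lay farther from one. Transcription running on from an upstream gene stays open for these genes, as set out below. The largest falls under the same limit were in ZBTB42 (-5.06), HSPA8 (-4.96 ± 0.29), HCAR1 (-4.95), ZNF318 (-4.86), LRRN3 (-4.81), SOWAHC (-4.78), SHISA2 (-4.62) and PBDC1 (-4.44). HSPA8, the constitutive HSC70 chaperone, went from 1730 ± 808 to 55.7 ± 7.3 CPM (SD, n = 2).

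CCN1 rose (2.05 ± 0.20, adjusted p = 1.3e-06) from 19.4 ± 5.9 to 80.5 ± 15.3 CPM (SD, n = 2), opposite to its fall in MCF-7. CCN2 was at least 3.65-fold lower, with 0 counts against 17, and its call was lost without DMSO replicate 1 (0.10), PIK75 replicate 1 (0.078) or PIK75 replicate 2 (0.11). MYC rose (1.68 ± 0.20) and so did ESR1 (1.35 ± 0.15), while CDK7 (-1.55 ± 0.18, adjusted p = 5.9e-06), CCND1 (-2.35 ± 0.19), TEAD4 (-1.30 ± 0.17; ENSG00000197905, chromosome 12 at 2959330–3040676, plus strand), PGR (-1.05 ± 0.21) and YAP1 (-0.77 ± 0.14; ENSG00000137693, chromosome 11 at 102110447–102233424, plus strand) fell. E2F1 fell (-0.47 ± 0.15) with its call lost without DMSO replicate 1 (0.11), PIK75 replicate 1 (0.074) or PIK75 replicate 2 (0.054) and with upper-quartile factors (0.35). MCL1 (-0.09), WWTR1 (-0.15, ENSG00000018408, chromosome 3 at 149517235–149736714, minus strand), CDK6 (0.01), RB1 (-0.03), CCNE1 (-0.33) and ANKRD1 (1.55) were not called. With totals alone CDK6 was called as a fall by the quasi-likelihood test (-0.65, adjusted p = 0.036).

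Histone genes rose in 40 of 41 cases (median 3.97, camera adjusted p = 1.2e-24, adjusted p = 0.64 with an estimated correlation), H2AC11 at least 184-fold. Ribosomal protein genes rose in 73 of 78 cases (median 1.30, 7.7e-12 and 0.65) and mitochondrially encoded protein genes in 13 of 13 (median 1.77, MT-CO1 2.63). Of 35 G2/M and mitosis genes 28 fell and 3 rose (TTK -3.84, KIF11 -2.74; 2.3e-09 and 0.64), and 21 of 35 G1/S genes fell (PCNA -4.38, CLSPN -3.26; 2.0e-04 and 0.64), while 7 G1/S genes rose, or 4 in each fit without 1 library. Homologous recombination genes fell in 21 of 33 cases and rose in 1, including EXO1 (-2.61), BARD1 (-2.55) and BRCA2 (-2.50). Heat-shock genes fell in 14 of 20 cases. CDK-activating kinase and transcriptional CDK genes split, with 9 up and 14 down (camera adjusted p = 0.063), CDK12 at -2.49 and GTF2H4 at 2.91. Immediate-early genes split as well, with 8 up and 11 down, a balance that turned to 10 up and 8 down with upper-quartile factors. DUSP5 (-5.82) and DUSP6 (-4.46) fell and ATF3 (2.73) rose. Without PIK75 replicate 2 DUSP6 had -9.41, a fitted value at or near 0 counts and no fold.

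YAP/TAZ target genes under PIK75 split into 6 up and 7 down of 18, with a median of 0.35, a mean of -0.23 and a camera adjusted p of 0.84 toward lower values, and the median turned to -0.32, with 4 up and 8 down, with totals alone. AMOTL2 (2.33) rose and ARHGEF17 (-2.11) fell. Hippo components fell in 16 of 29 cases and rose in 5 (FAT1 -3.24, SAV1 -2.35). The CDK4/6-RB list had 7 up and 8 down, with CDKN1B at 2.43. It turned to 7 up and 5 down with upper-quartile factors, and 4, 5 and 5 were down without DMSO replicate 1, PIK75 replicate 1 or PIK75 replicate 2. Markers of other cell types moved with PIK75. Fibroblast markers rose in 4 of 5 cases (COL1A2 ratio 308, 95% counting interval 54.6 to 12220; PDGFRB at least 19.7-fold) and leukocyte and endothelial markers in 3 of 4 with 1 down (PECAM1 ratio 233, 41.2 to 9272; CD14 ratio 66.3, 22.2 to 326, with 9.21 log2 units without DMSO replicate 2). Their fitted medians of 5.79 and 6.69 became 4.30 and 5.15 with genes at 0 set to their bound. The 9.21 for CD14 is a fitted value near 0 counts and no fold. Markers near 0 counts in DMSO passed the filter only through a treated group, so that most tested ones rose follows largely from the filter. Markers that did not pass are left out of these counts. The self-test recovered 15% of 1.5-fold and 99% of 3-fold changes.

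The sixth comparison asked how THZ1 changed the same T-47D cells. THZ1 changed 10034 of 18239 genes (5223 up, 4811 down), and 3375 rose and 2628 fell at least 2-fold. Up calls made up 52.1% with TMM and 20.8% with totals alone (2370 up, 9050 down), where the median over all genes was -0.68 against 0.00. Of genes with at least 10 CPM and no overlap between groups, the largest rises were in KRT36 (ratio 629, 95% counting interval 112 to 24900) and RNF151 (547, 97.7 to 21670), each from 1 DMSO count, then in ARC (5.97), S100A14 (5.72), FOS (5.44), SGK1 (5.06), SIK1 (4.98) and FEM1A (4.97). ARC and FOS are immediate-early genes. The largest falls among such genes were in FAM111B (-3.43), KRCC1 (-3.11), ZBTB37 (-2.99), SLC16A14 (-2.96), KIF24 (-2.86), SLFN11 (-2.83), BRCA2 (-2.76) and KNSTRN (-2.75).

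CCN1 (3.24 ± 0.21, adjusted p = 2.2e-07) and CCN2 (4.93 ± 0.44, adjusted p = 3.1e-06) rose under THZ1, to 184 ± 13.2 and 9.67 ± 1.29 CPM (SD, n = 2), and ANKRD1 rose from 4 to 51 counts (4.02 ± 0.56). MYC rose (1.37 ± 0.20). CDK7 fell (-1.02 ± 0.18, adjusted p = 3.2e-04), as did ESR1 (-0.89 ± 0.14), PGR (-1.64 ± 0.21), CDK6 (-1.54 ± 0.25), TEAD4 (-0.85 ± 0.17), E2F1 (-1.33 ± 0.15) and CCNE1 (-0.79 ± 0.23, lost without DMSO replicate 2 at 0.087). YAP1 had 0.01 and MCL1 0.14. With totals alone both were called as falls by the quasi-likelihood test, YAP1 at -0.71 (adjusted p = 8.5e-04) and MCL1 at -0.58 (adjusted p = 0.0040). WWTR1 (-0.29), RB1 (-0.45) and CCND1 (0.08) were not called. Among the fits without 1 library, WWTR1 was called only without THZ1 replicate 1 (-0.66), and RB1 and CCND1 only without THZ1 replicate 2 (-1.03 and 0.31). With totals alone CCND1 was called as a fall by the quasi-likelihood test (-0.62, adjusted p = 0.019).

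YAP/TAZ target genes rose in 8 of 18 cases and fell in 3 (median 0.45, mean 1.01, camera adjusted p = 0.070, adjusted p = 0.53 with an estimated correlation, fry adjusted p = 0.0073), but turned to 6 up and 9 down with totals alone. Besides CCN1, CCN2 and ANKRD1, the members GADD45A (2.62), TGFB2 (2.19), AXL (1.54), PTPN14 (0.69) and CRIM1 (0.35) rose, while ARHGEF17 (-1.25), FJX1 (-1.08) and LATS2 (-0.56) fell. Camera called the list without DMSO replicate 1 (0.038) and with only the libraries compared (0.038), and not without DMSO replicate 2 (0.094), THZ1 replicate 1 (0.18) or THZ1 replicate 2 (0.061). Hippo components fell in 14 of 29 cases and rose in 6, with 9 down and 3 up without DMSO replicate 1.

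**Figure D3:**
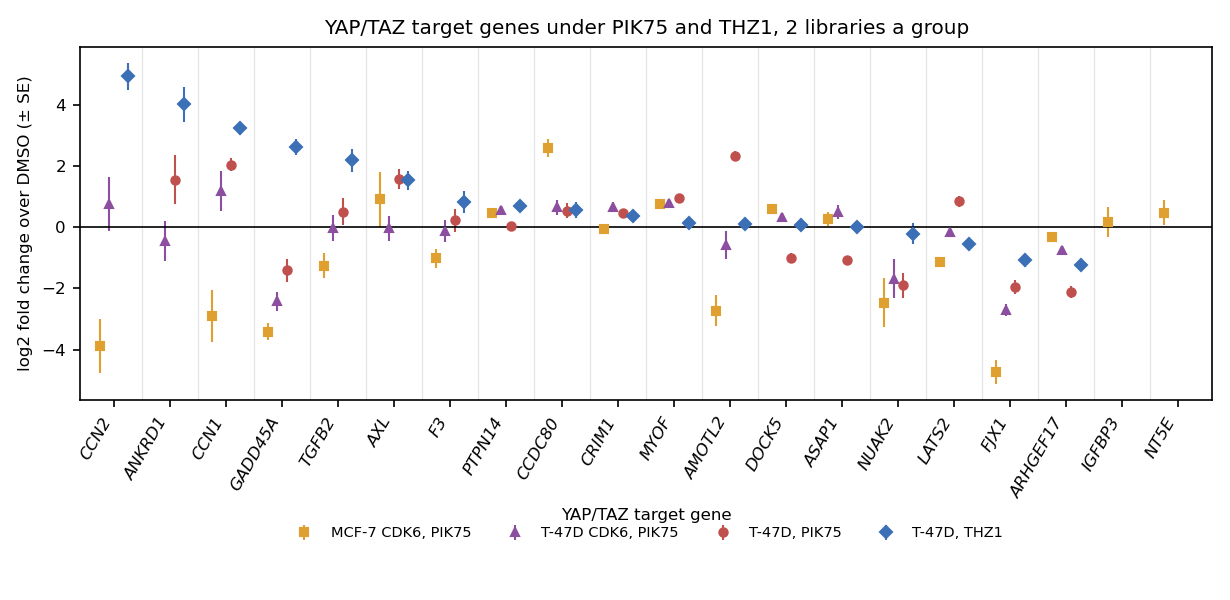
Log2 fold change of YAP/TAZ target genes (points, bars are standard errors) in the 4 inhibitor comparisons with DMSO, ordered by THZ1, leaving out values with a standard error of 1 or more. CCN1 rose under THZ1 (3.24) and under PIK75 in T-47D (2.05) and fell under PIK75 in MCF-7 with CDK6 (-2.91); the list as a whole turned direction with totals alone under THZ1.

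Immediate-early genes rose under THZ1 in 20 of 26 cases and fell in 2, or 20 and 3 adjusted over the list alone (median 2.38, camera adjusted p = 2.2e-08, adjusted p = 0.53 with an estimated correlation), with JUNB (4.61), IER3 (4.18) and IER2 (4.04). Homologous recombination genes fell in 22 of 33 cases and rose in 1 (5.4e-06 and 0.53), as BRCA1 (-2.61), EXO1 (-2.50) and BLM (-2.47) did. G1/S genes fell in 23 of 35 cases and rose in 5, or 9 without THZ1 replicate 1 (CDC6 -2.70, PRIM1 -2.65; 2.7e-05 and 0.56). KRAB zinc-finger genes fell in 31 of 49 cases and rose in 3 (3.1e-05 and 0.58). Histone genes rose in 36 of 41 cases (median 2.56, or 2.49 with genes at 0 set to their bound; 5.0e-13 and 0.53), H2BC11 at least 14.5-fold. Ribosomal protein genes rose in 74 of 78 cases (median 1.16, 1.2e-17 and 0.56), RPLP2 by 1.69, and all 13 mitochondrially encoded protein genes rose (median 1.84, MT-CO2 2.16). Glycolysis genes rose in 15 of 24 cases and fell in 5 (GAPDH 1.85; 0.0096 and 0.53), with falls of 1, 3, 8 and 3 without DMSO replicate 1, DMSO replicate 2, THZ1 replicate 1 or THZ1 replicate 2. In the transcriptional CDK list 6 rose and 12 fell with a median of -0.06 and a mean of 0.12. With upper-quartile factors 9 rose and 9 fell, with a median of 0.08. CDK11A (3.58), HEXIM1 (2.36), POLR2A (1.97) and BRD4 (1.67) rose in it. HEXIM1 restrains the elongation kinase CDK9 (background). Of the 5 fibroblast markers that passed the filter 3 rose, and CD14 rose at a ratio of 41.8 (13.8 to 206). Without DMSO replicate 2 CD14 had 8.57 log2 units, a fitted value near 0 counts and no fold. The self-test recovered 29% of 1.5-fold and 99% of 3-fold changes.

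**Figure D4:**
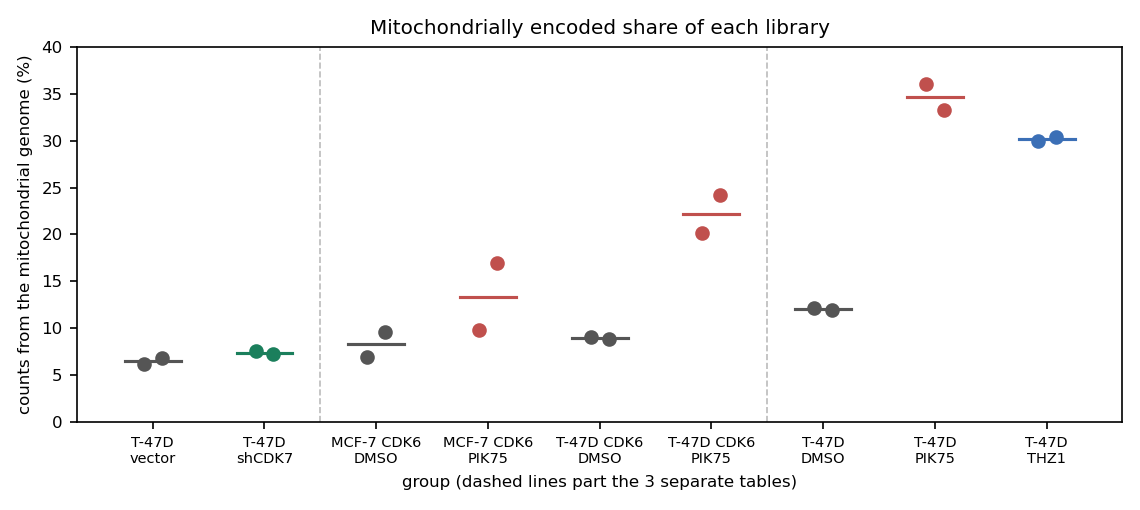
Percent of all counts from mitochondrially encoded genes in each of the 18 libraries; points are libraries and lines are group means. The share rose from at most 12.1% under DMSO to 36.0 and 33.3% under PIK75 and 29.9 and 30.4% under THZ1 in T-47D cells, and hardly moved with the knockdown (6.15 to 7.50%).

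The seventh comparison set PIK75 directly against THZ1 in T-47D cells. It called 10334 genes (5189 higher under PIK75, 5145 lower), 3861 and 3116 of them at least 2-fold. Immediate-early genes were lower under PIK75 in 19 of 26 cases and higher in 2 (median -2.57, camera adjusted p = 4.4e-07, at least 0.57 for every list with an estimated correlation), with FOS at -5.66 and DUSP6 at -5.46. Without PIK75 replicate 2 DUSP6 had -10.40, a fitted value at or near 0 counts and no fold. Cholesterol synthesis genes were lower in 17 of 23 cases (SQLE -2.83), or 11 without PIK75 replicate 1 or PIK75 replicate 2. Heat-shock genes were lower in 15 of 20 cases (HSPA8 -4.05, HSPA1A -3.68). Histone genes were higher in 30 of 41 cases and lower in 3 (median 2.00, H3C8 4.23). Oestrogen receptor targets were higher in 17 of 30 cases and lower in 4 (RARA 2.25, TFF1 -3.22), and ESR1 was higher by 2.24 ± 0.15. POLR2A (-3.22) and HEXIM1 (-3.17) parted the compounds in the transcriptional CDK list (5 higher, 16 lower of 30).

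YAP/TAZ targets were lower under PIK75 than under THZ1 in 11 of 18 cases and higher in 3 (median -0.87, camera adjusted p = 0.060). Camera called the list with the replicate block, with no filter and with upper-quartile factors (adjusted p = 0.047, 0.028 and 0.049). At 10 CPM its direction turned (adjusted p = 0.87). CCN1 (-1.19), ANKRD1 (-2.46), YAP1 (-0.78) and GADD45A (-4.03) were lower, CCN2 was at least 113-fold lower, and AMOTL2 (2.22) was higher. CCND1 (-2.44) was lower, and CDK6 (1.55), E2F1 (0.87) and PGR (0.59) were higher, PGR losing its call without PIK75 replicate 1 (0.22), PIK75 replicate 2 (0.10) or THZ1 replicate 2 (0.060). CDK7 (-0.53, adjusted p = 0.026) and TEAD4 (-0.45, adjusted p = 0.045) lost their calls without PIK75 replicate 1 (0.16 and 0.17), PIK75 replicate 2 (0.075 and 0.098) or THZ1 replicate 1 (0.24 and 0.12), and with totals alone (0.097 and 0.12). ANKRD1 was not called by DESeq2 (0.056). RB1, MCL1, WWTR1, MYC and CCNE1 were not called. Among the fits without 1 library, RB1 was called only without THZ1 replicate 2 (0.97). With at least 10 CPM and no overlap between groups, the largest rises were in genes with 0 counts under THZ1. They were PDE1B (at least 558-fold), EYA4 (353), C4orf54 (315), MGAM2 (288), ARHGEF15 (189), RSPO2 (181), KCTD4 (155) and INMT (145). IER5L (-6.50), TUBB2A (-6.19), MAFB (-5.95), DIPK2A (-5.90), TBX3 (-5.71), SOWAHC (-5.36) and SLC10A3 (-4.94) had the largest falls under the same limit beside FOS. The self-test recovered 21% of 1.5-fold and 100% of 3-fold differences.

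PIK75 and THZ1 shared 3494 genes up and 3356 down in T-47D cells, against 1992 and 1566 for independent calls, while 394 rose under PIK75 and fell under THZ1 and 446 did the reverse. The split depended on scaling, with 1409 shared up and 7016 shared down with library totals alone (571 and 4315 for independent calls). With TMM the correlation across genes was 0.491 (Spearman 0.547). The same 2 DMSO libraries served both and could not be split, so part of the excess may come from shared controls. In 20 simulations of unchanged groups with shared controls the mean correlation was 0.461 with a covariance of 0.0363 and 0 overlapping calls, against an observed covariance of 1.788. The simulation drew every group from the DMSO means, so genes at 0 in DMSO had no counts in it, while these had the largest rises under PIK75. The simulated covariance may thus understate the part due to shared controls, and the difference of 1.752 is not an estimate of the shared effect. With separate controls, PIK75 in the CDK6 lines shared 3141 genes up and 3674 down (1226 and 1365 for independent calls; correlation across genes 0.661). PIK75 in T-47D with and without CDK6 overexpression shared 3111 up and 3190 down (1526 and 1616; correlation across genes 0.706), although the experiments were separate and CDK6 dose cannot be parted from experiment.

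The last question was whether genes that moved with the knockdown also moved with the compounds. With no knockdown calls, the 200 genes up and the 200 down with the lowest p were used as sets. By camera no set passed in any inhibitor comparison (lowest adjusted p = 0.22, and at least 0.816 with an estimated correlation). By fry the set down with knockdown leaned upward in T-47D under PIK75 and THZ1 (adjusted p = 0.0387 in each), with 72 of 158 members up and 44 down under PIK75 against 60.2 and 51.4 for independent calls. Under THZ1 the counts were 48 up and 37 down, close to the 45.2 and 41.7 for independent calls. With sets from the fit without vector replicate 2, an alternative chosen after seeing the data, the fry call was lost under PIK75 (adjusted p = 0.67, 65 up, 64 down) and THZ1 (0.069). Correlations of fold changes across genes between the knockdown and the inhibitor comparisons ran from -0.14 to -0.03, and from -0.01 to 0.04 without vector replicate 2. A likeness between CDK7 loss and the compounds was thus not seen across genes, though the spread of the vector group limits what these sets can show.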

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

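The tests for a wrong label, for library depth in both patterns, for relative scaling and for read-through as the whole cause were chosen only after the result was seen, and so were the window sizes and the rule for a raised silent gene.

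The effect of PIK75 differed between the 2 CDK6 lines by a direct test of that difference for 3107 genes. Among the genes given in every comparison the differences (T-47D minus MCF-7, log2) were 4.10 for CCN1, 4.64 for CCN2, 2.20 for MYC, 1.81 for MCL1, 1.64 for CCNE1, 0.82 for CCND1, 0.72 for WWTR1, 0.62 for ESR1, 0.48 for RB1 and -0.82 for CDK7. Line and CDK6 level differ together, since CDK6 lay at 382 and 296 CPM in T-47D and at 68.7 and 58.8 CPM in MCF-7. Genes low under DMSO in T-47D, such as CCN2, also had less room to fall there. No biological explanation was tested.

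Vector replicate 2 stood apart from the other 3 libraries of its experiment, with a median log2 ratio over vector replicate 1 of 1.754 for the unfolded protein and integrated stress response list (23 of 33 members above 1) and HSPA5 at 13202 against 1509 CPM. Library depth was argued against, since the knockdown pair differs more in depth (1.33-fold against 1.27-fold) and had a median ratio of 0.07523 for the list. A smooth fit on GC content and gene length took up 0.761% of the variance across genes and left 1.686, which argues against a trend in them as the whole cause. A wrong label of an MCF-7 or a knockdown library was argued against by MTAP at 23.9 CPM (at most 0.732 in MCF-7) and by CDK7 at 3.389 times the higher knockdown library. The design gives no group that separates the vector replicates, so no biological explanation was tested.

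Genes at 0 counts in both T-47D DMSO libraries (31400) were raised by PIK75 in 881 cases and by THZ1 in 68, while 33 and 5 genes went to 0 in the reverse direction. More sequencing depth was argued against, since the lower PIK75 library still detected 5233 more genes than the higher DMSO library after thinning. Of silent genes with at least 2 kb of exon, 53.29% stayed at 0 in both PIK75 libraries. This argues against genomic DNA dense enough to reach nearly all such genes. It cannot decide on a low level, since the reads that such a level would give were not worked out. Transcription running on from an expressed upstream gene had the values it needs, as silent genes within 20 kb downstream of an expressed gene, and not also head to head with one, were raised 2.616 times as often as those only head to head (10.42% of 1267 against 3.982% of 1331, Fisher exact p = 1.3e-10). Expressed meant at least 10 CPM in DMSO. By that rule 30.65% of the raised genes lay outside expressed genes and over 200 kb from an expressed gene upstream. Upstream genes below 10 CPM in DMSO, also those raised by PIK75, were not counted, so this share cannot exclude read-through as the whole cause. Read-through may therefore account for part of the raised genes, and whether it accounts for the rest stays open.

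YAP/TAZ target genes rose under THZ1 in T-47D in 8 of 18 cases. Relative scaling stays open, because with library totals alone the median of the list was -0.2643, with 6 up and 9 down, although 6 of those 8 members still rose. A gain of short over long genes stays open as well, since the 8 members lay at percentile 89.61 of 10000 lists matched on genomic span and expression (mean 5.583, central range 2 to 9). The number of members that rose may thus be no larger than among other genes of like span and expression. How far the members rose was not compared. Matching used expression averaged over all libraries, THZ1 among them, so the matched genes may lean toward genes that rose. No biological explanation was tested.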

How the results depend on the processing

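The fits without mitochondrial genes were chosen only after the data were seen, and all other tests here were planned. Of 341 called results for named genes, 309 kept their call and direction in every alternative. Among 5745 values of named genes, leaving out 1 library left 1449 of the called values the same, weakened 93 and reversed 1, and other settings left 3252 the same, weakened 38 and reversed 2. Of values not called, 228 stayed the same, 43 became stronger and 34 reversed without 1 library, and 516, 44 and 45 did so in other settings. A lone library left in a group is assumed to vary like the other groups, and fewer samples lower the power by construction. Otherwise the cause was not tested.

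Knockdown calls were 499 with no filter on low counts and 43 with DESeq2. CDK6 had -7.0e-05 with totals alone, -0.0163 with upper-quartile factors, -0.0081 at 1 CPM and -0.0075 with the replicate block, and MYC -0.0065 with upper-quartile factors, -0.0163 at 10 CPM and -0.0675 with the block. Without single libraries the calls ranged from 0 to 4257, and log2 values from -0.22 to 0.97 for CCN1, -0.57 to 2.58 for CCN2, -0.23 to 0.22 for CDK6, -0.57 to 0.45 for MYC, -0.34 to 1.02 for CCND1, -0.24 to 0.11 for YAP1, -0.66 to 0.016 for ANKRD1, -0.13 to 1.05 for TEAD4, -0.030 to 0.31 for RB1, -0.22 to 3.11 for E2F1 and -0.094 to 2.48 for CCNE1.

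For PIK75 in MCF-7 with CDK6, the YAP/TAZ list passed by fry (median -0.66, adjusted p = 0.033). YAP1 had 0.029 with DESeq2 size factors, 0.21 with upper-quartile factors, 0.0029 at 10 CPM, 0.0038 with DESeq2 and 0.015 without mitochondrial genes. With totals alone CDK6 had -0.25, PGR -0.23 and RB1 -0.20, and with no filter -0.047, -0.029 and -0.0046. Upper-quartile factors gave 0.11 for WWTR1, 0.087 for TEAD4 and 0.090 for E2F1. Without single libraries YAP1 ran from -0.15 to 0.11, CDK6 from -0.20 to 0.24 and PGR from -0.17 to 0.51.

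For PIK75 in T-47D with CDK6, totals alone gave -0.0081 for WWTR1, -0.21 for YAP1 and -0.43 for E2F1. Upper-quartile factors gave 0.056 for CCND1, and leaving out mitochondrial genes -5.7e-04 for E2F1. Of these values only that of E2F1 with totals alone was called by the quasi-likelihood test (adjusted p = 0.012). Without single libraries E2F1 ran from -0.088 to 0.19, CCN1 from -1.01 to 1.99, CCN2 from -1.44 to 1.56 and the YAP/TAZ list from -0.23 to 0.16. The count of genes differing between the lines ran from 1480 to 3492, and GJC1 from -7.36 to 1.66.

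For PIK75 in T-47D, the YAP/TAZ list turned upward by its test with fry (0.35), at 10 CPM (0.45) and with only the libraries compared (0.33). RB1 had 0.018 with DESeq2 size factors, 0.27 with upper-quartile factors, 0.027 at 1 CPM and 0.17 at 10 CPM. CDK6 had -0.65 with totals alone, -0.17 with no filter, -0.013 with DESeq2, -0.0046 with only the libraries compared and -0.0021 without mitochondrial genes. Of these CDK6 values only that with totals alone was called, by the quasi-likelihood test (adjusted p = 0.036). MCL1 and WWTR1 had 0.21 and 0.15 with upper-quartile factors and 0.11 and 0.047 at 10 CPM. Calls fell to 7252 at 10 CPM, where fewer genes are tested. Without single libraries CDK6 ran from -0.049 to 0.045, RB1 from -0.091 to 0.011 and the YAP/TAZ list from 0.19 to 0.29.

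For THZ1, the YAP/TAZ list passed by fry (0.45) and with only the libraries compared (0.47, adjusted p = 0.038). YAP1 had -0.0046 with DESeq2 size factors, -0.71 with totals alone, -0.19 with no filter and -0.051 with DESeq2. MCL1 had -0.58 and -0.054, and CCND1 -0.62 and -0.11, with totals alone and with no filter. With totals alone YAP1, MCL1 and CCND1 were called as falls by the quasi-likelihood test (adjusted p = 8.5e-04, 0.0040 and 0.019). With no filter they were not called. Calls fell to 6453 at 10 CPM. Without single libraries YAP1 ran from -0.18 to 0.055, MCL1 from -0.076 to 0.21, CCND1 from -0.33 to 0.31 and the YAP/TAZ list from 0.21 to 0.71.

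For PIK75 against THZ1, the YAP/TAZ list passed by fry (-0.87), with upper-quartile factors (-0.70), with no filter (-0.65) and with the replicate block (-0.85), and turned by its test at 10 CPM (-0.63, adjusted p = 0.87). Calls fell to 5326 at 10 CPM. Without single libraries MYC ran from -0.073 to 0.63, WWTR1 from -0.075 to 0.44 and the list from -1.08 to -0.55. The correlation of PIK75 with THZ1 across genes was 0.492 with DESeq2 size factors and 0.540 with totals alone.

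With the replicate number as a block, calls were 0 for the knockdown, 10473, 9773 and 3491 in the CDK6 experiment and 12667, 9775 and 10009 in the inhibitor experiment. Deviations of replicates with the same number correlated at 0.243 for the knockdown, 0.534 for MCF-7, 0.182 for T-47D with CDK6, 0.139 and 0.027 for DMSO with PIK75 and with THZ1, and -0.285 for PIK75 with THZ1. Between groups of different lines the correlations ran from -0.021 to 0.09. The numbers were not taken to pair the samples, since 2 pairs cannot establish this. The block was 1 term shared by all libraries of an experiment. It could not take up a pairing within 1 line alone, so the counts with the block do not test for that. Depth limits genes near 0, where 3 counts in a library equal 0.0493 to 0.168 CPM.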

Other observations

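The windows and place classes for silent genes, and the bins of gene span, were tests chosen only after the result was seen.

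Mitochondrial ribosomal RNA took up 1.06 and 1.13% of the counts in T-47D under DMSO, 8.49 and 7.72% under PIK75 and 5.82 and 5.85% under THZ1. The share of all mitochondrial transcripts rose in the other setting of T-47D as well, from 8.99 and 8.79% to 20.2 and 24.2% with CDK6. In MCF-7 it rose from 6.93 and 9.59% to 9.76 and 16.9%. A share also rises where the other transcripts are lost, and the data cannot part this from a gain.

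In plain T-47D cells short coding genes gained on long ones under both compounds. Of genes spanning under 10 kb, 47.3% rose under PIK75 and 41.7% under THZ1, against 25.4 and 17.6% of genes spanning over 100 kb (Spearman correlation of span with fold change across genes -0.171 and -0.194). With CDK6 overexpression PIK75 gave another picture. In T-47D 27.4% of short and 31.1% of long genes rose and 33.5 and 17.6% fell, the reverse gradient (0.115), and in MCF-7 32.7 and 25.1% rose and 32.5 and 23.1% fell (0.0324).

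Silent genes just past expressed genes were raised by PIK75 in T-47D at the highest rate. Each silent gene was given 1 place, with genes overlapping an expressed gene set apart first and head-to-head neighbours not considered. Of those starting within 20 kb downstream of an expressed gene on their strand 12.8% were raised (136 of 1065), of those further out but within 200 kb 6.28% (376 of 5984), of remote ones 1.35% (270 of 20036), and of those overlapping an expressed gene on the same or the other strand 1.42 and 3.16%. THZ1 raised far fewer silent genes, 12 of the 1065 within 20 kb, 14 of the 5984 further out, 16 of the 20036 remote ones and 13 in each of the overlapping classes. Against head-to-head genes its downstream ratio was 1.576 on 9 and 6 raised genes (Fisher exact p = 0.44), too few to settle an excess, and 73.16% of the longer silent genes stayed at 0.

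RASL11A rose under PIK75 in both CDK6 lines (4.74 and 6.95), beside 5.8S ribosomal RNA. Total RNA was extracted, which does not tell how RNA was selected for the libraries. The replicates of the vector group scattered most, with a chi-square per gene of 328 (correlation of log2 CPM 0.960) against 6.09 to 48.8 elsewhere.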
